A study of Homo sapiens with 6 samples.

How the data were processed

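Gene expression was measured in LNCaP cells, a human prostate cancer cell line that expresses prostate-specific membrane antigen (PSMA, the product of FOLH1), on 1-colour Affymetrix arrays. Total RNA was extracted with Trizol and biotinylated cRNA was prepared from 2 ug of it, per the labels' protocols. The 6 arrays comprised 3 of control cells, described as untreated, and 3 of cells in which PSMA was knocked down by a transduced retroviral short hairpin RNA. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the controls carried an empty vector, nor whether the replicates were separate cultures, so the p-values measure the spread between these arrays, which may be technical.

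The values analysed were probe set intensities on a linear scale, deposited by the authors after GCRMA (background correction, normalization between arrays and summary per probe set), per the submitters' processing notes. The GCRMA version and settings are not given in the sources used here. The linear scale was read from the deposited intensities, which ran from 3.82 to 22631, with the same highest value in 5 of the 6 arrays. The median intensity per array was between 48.2 and 50.3. Array data carry no read depth, and the number of arrays limits the precision.

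The 22277 probe sets were named from the platform's annotation table, updated where needed against RefSeq gene names of assembly GRCh38.p14, which changed 0 symbols. Of these, 62 were control probe sets, 19064 were paired with 1 symbol, 1043 with several and 2108 with none. Probe sets with several symbols or none were left out of the gene tests, except that those paired with FOLH1 and FOLH1B are given by probe set. Intensities were log2-transformed. A probe set was kept where at least 3 of the 6 arrays reached log2 4 (an intensity of 16), and the probe set with the highest mean over all arrays stood for its gene, which left 9241 genes. Differences are knockdown minus control, from limma 3.58.1 (lmFit and eBayes, in R 4.3.3), with Benjamini-Hochberg adjustment over all genes tested. A gene rose or fell where its adjusted p was under 0.05, and was counted as changed at least 2-fold where the fitted change also reached that size.

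Before the data were examined, 27 functional gene lists and 8 cell type marker lists were fixed, as were the tests and the alternatives. Each of the 31 lists with at least 5 measured members was tested with camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The genes to name were also fixed by rule. FOLH1 came first, then the 10 largest rises and the 10 largest falls among genes changed at least 2-fold whose arrays did not overlap between groups. From each list up to 4 members changed at least 2-fold were taken, or otherwise up to 2 members with the largest change, with all measured PSMA homologues. Some listed items are not reported here.

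The tests were checked on simulated arrays with the signal levels and spreads of these 9241 genes, in which 200 genes were changed. At an adjusted p under 0.05, 44% of genes changed 1.25-fold, 82% of those changed 1.5-fold and 100% of those changed 2.5-fold or 4-fold were recovered, 50 genes each, and 11 unchanged genes passed. In a second simulation, all 3 lists shifted by 0.3 on the log2 scale were called in the right direction, and 0 of 28 unshifted lists were called. Both simulations drew each gene independently, so they could not test whether the preset correlation is too low for these lists. They also changed far fewer genes than the 3319 with an adjusted p under 0.05 in the data. Alternatives covered the filter, a floor on low values, normalization between arrays, the handling of several probe sets per gene, the variance model, array weights, the replicate number as a block, the size threshold, the set test and leaving out each array. Control probe sets were compared between groups with exact permutation tests, two-sided.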

Results

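Expression was compared between control LNCaP cells and LNCaP cells with PSMA knocked down, with 3 arrays per group. PSMA is a membrane carboxypeptidase that releases glutamate from folates and from N-acetylaspartylglutamate, and the comparison asks which transcripts differ when prostate cancer cells have less of it. Replicate arrays lay close together: the SD of log2 differences between 2 arrays was 0.157 to 0.188 within groups and 0.331 to 0.350 between groups.

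The target was lower in all knockdown arrays. The 3 bright probe sets paired with both FOLH1 and its near-identical copy FOLH1B fell, with log2 fold changes of -2.27, -2.23 and -2.72 and a mean of -2.41. The first of them measured 12.51 ± 0.04 (SD, n = 3) in control and 10.24 ± 0.07 (SD, n = 3) in knockdown cells, 4.82-fold lower at a limma adjusted p of 1.1e-06. A probe set paired with FOLH1B alone fell by 2.28 on the log2 scale; because the copies are so alike, these probe sets cannot be ascribed to either gene. The 1 probe set paired with FOLH1 alone was dim, at 6.38 ± 0.05 in control and 5.59 ± 0.40 in knockdown cells (SD, n = 3), a log2 fold change of -0.79 (SE 0.18, adjusted p = 0.011). That call was lost when values under log2 4 were raised to 4 (adjusted p = 0.0771). No value of this probe set lay under log2 4, so the loss came through the other genes in the test. In knockdown cells the shared probe sets still averaged 7.82 or more on the log2 scale. Of the PSMA homologues, NAALAD2 and NAALADL1 rose slightly, with log2 fold changes of 0.49 and 0.26, both at low intensity.

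**Figure D1:**
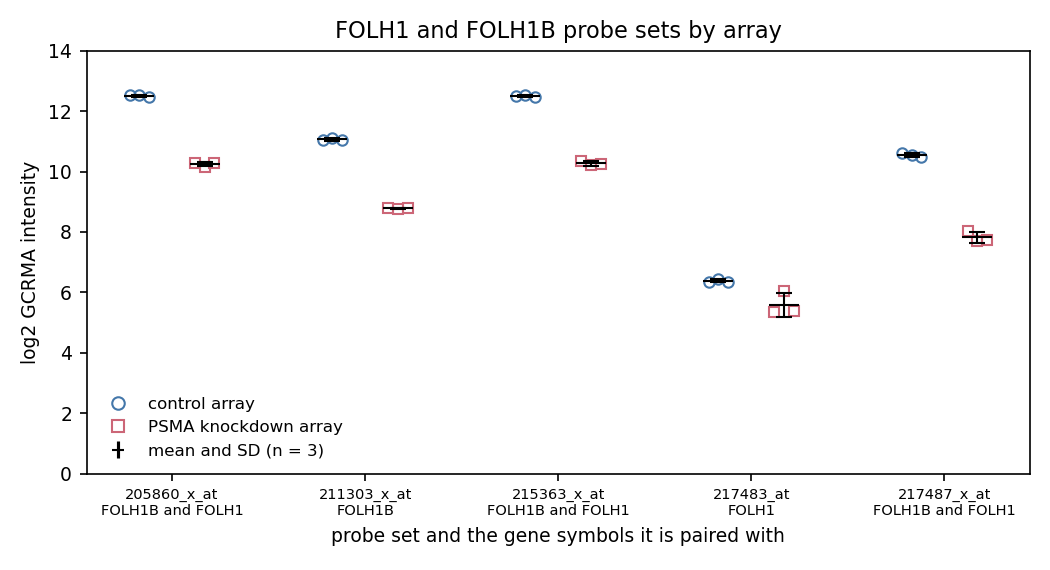
Log2 GCRMA intensity (vertical axis) of the 5 probe sets paired with FOLH1, FOLH1B or both (horizontal axis) in each control array (circles) and each PSMA knockdown array (squares), with the mean and SD of 3 arrays. The bright probe sets lie more than 2 log2 units lower in knockdown cells, while the dim probe set paired with FOLH1 alone differs by -0.79.

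Among 9241 genes, 80 were at least 2-fold higher and 93 at least 2-fold lower in knockdown cells. The largest rise was in NLGN4X, a postsynaptic adhesion protein, from 5.61 ± 0.21 to 9.77 ± 0.09 on the log2 scale (SD, n = 3), 17.9-fold at an adjusted p of 6.3e-07. The imprinted gene MEST rose 9.69-fold and BRINP1 8.81-fold, the latter from a control level under log2 4 (a log2 fold change of 2.44 with low values raised to 4). IGFBP3, which binds insulin-like growth factors, rose 7.23-fold, the kinase DAPK1 rose 7.19-fold and the reticulon RTN1 rose 6.85-fold. The peroxidasin PXDN, the transcription factor MAF and the focal adhesion protein PARVA rose 5.57-, 5.51- and 5.40-fold. The ETS factor ETV1 rose 7.32-fold on its brightest probe set, whereas its other probe sets each differed by 0.50 on the log2 scale. With the mean of all probe sets of a gene, the log2 fold changes were smaller for DAPK1 (1.54), MAF (1.75), PARVA (1.44) and ETV1 (0.95). This mean includes probe sets that failed the filter. DAPK1 had no other probe set past the filter, and the other ones past it for MAF and PARVA rose by 2.76 and 1.68.

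The largest fall was in PKIA, an inhibitor of protein kinase A, from 8.13 ± 0.09 to 4.24 ± 0.31 on the log2 scale (SD, n = 3), 14.7-fold at an adjusted p of 3.3e-06. The Golgi mannosidase MAN1A1 was 11.7-fold lower and the cancer-testis antigen PAGE1 11.4-fold lower. The receptor phosphatase PTPRK was 9.94-fold lower, to a knockdown level under log2 4, and with low values raised to 4 its log2 fold change was -2.47. SI (sucrase-isomaltase) was 6.82-fold lower, the guanylate cyclase subunit GUCY1B1 5.52-fold lower and the TGF-beta pseudoreceptor BAMBI 4.86-fold lower. Probe sets disagreed on the size of 3 of the 10 largest falls: MAN1A1 had log2 fold changes of -3.55 and -1.76, AQP3 of -3.33, -0.21 and -0.08, and SCCPDH of -3.20 and -0.75. For SCCPDH the second probe set stood for the gene when any control array was left out, with values from -0.81 to -0.69. Smaller changes were widespread, since 1793 genes rose and 1526 fell at an adjusted p under 0.05 regardless of size. Arrays did not overlap between groups for 49.4% of all genes tested, against 10% by chance. They did not overlap for any of the 173 genes changed at least 2-fold, which the selection of these genes largely ensures.

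**Figure D2:**
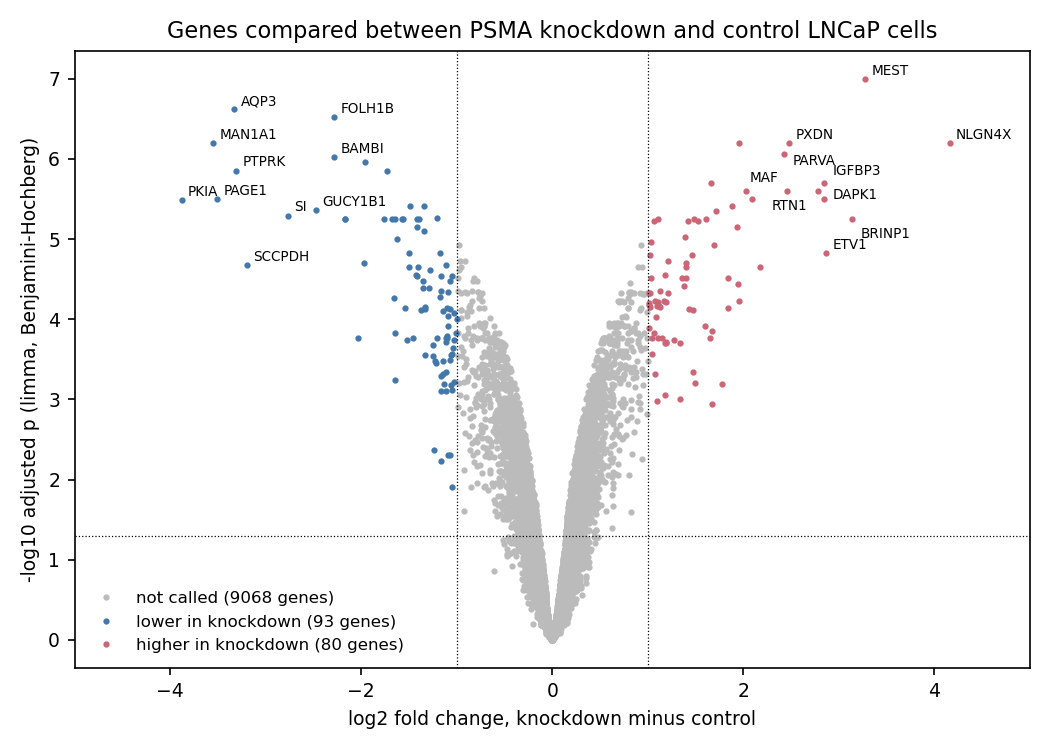
Log2 fold change of knockdown minus control (horizontal axis) against the negative log10 of the adjusted p (vertical axis) for each of 9241 genes; dotted lines mark a 2-fold change and an adjusted p of 0.05. The 80 genes higher and 93 genes lower in knockdown cells are coloured, and the 10 largest changes each way are named.

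The array's control probe sets also differed between the groups. All 18 probe sets for the hybridisation controls, bacterial and phage transcripts meant to be added after labelling, were lower in every knockdown array than in every control array, with means of 10.51 ± 0.13 against 11.34 ± 0.08 on the log2 scale (SD, n = 3). The signal of 5′ relative to 3′ probe sets was lower in knockdown arrays for beta-actin, by a log2 difference of -0.82, and for the poly-A control dap, a bacterial RNA meant to be added before labelling, by -0.97. The poly-A controls phe, thr and lys differed by -0.49, -0.40 and -0.33, and GAPDH by -0.10. In an exact permutation test, two-sided, each of these 7 measures reached p = 0.1, the smallest that 3 arrays against 3 allow. These controls separated the arrays by group, so array processing and group cannot be told apart.

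**Figure D3:**
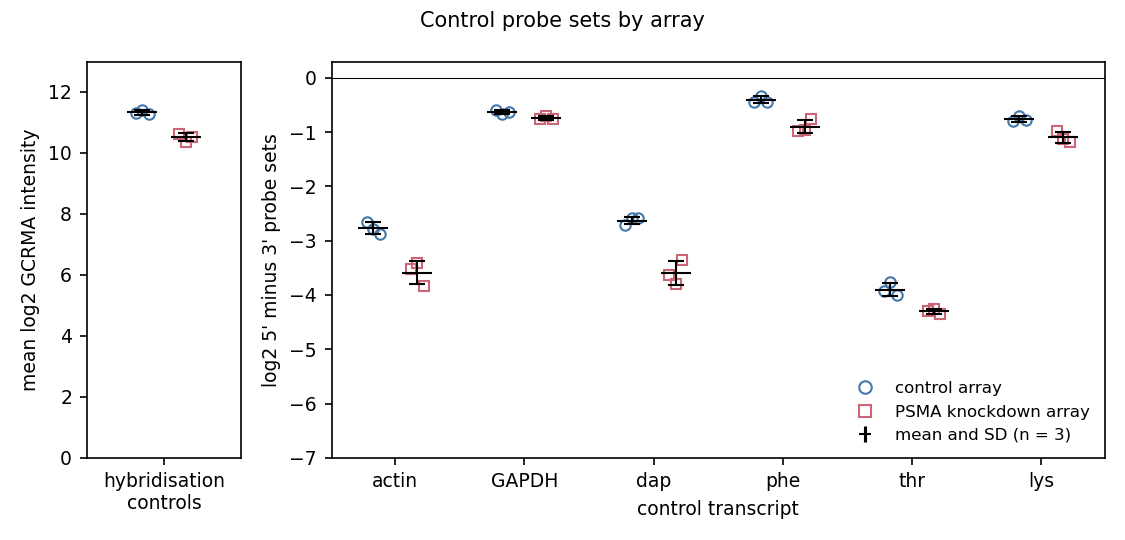
Left, mean log2 GCRMA intensity of 18 hybridisation control probe sets; right, log2 difference between 5′ and 3′ probe sets of beta-actin, GAPDH and 4 poly-A controls (vertical axes), for each control array (circles) and knockdown array (squares) with the mean and SD of 3 arrays. All knockdown arrays lie below all control arrays for the hybridisation controls and for dap.

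Genes of 5 lists moved lower together, with medians from -0.19 to -0.78 on the log2 scale, within the size of the 5′ to 3′ differences of the control transcripts. These calls were made at camera's preset correlation and were lost when camera estimated the correlation (adjusted p = 0.193 to 0.375). The estimates for androgen-repressed genes and cholesterol synthesis, -0.032 and 0.002, lay under the preset 0.01. A higher correlation therefore cannot be why those calls were lost. In the amino acid response, 19 of 30 measured genes fell and 1 rose (23 and 2 adjusted over the list alone), with a median log2 fold change of -0.28. Among them were the serine synthesis enzyme PSAT1 (-0.89) and the cystathionine synthase CBS (-0.65), and none of the 30 changed 2-fold. In the unfolded protein response, 12 of 18 genes fell and 1 rose (13 and 2 adjusted over the list alone), including the chaperones DNAJC3 (-1.13) and PDIA3 (-1.09), while EDEM1 rose by 0.63. In cholesterol synthesis 9 of 17 genes fell and 0 rose (10 and 2 adjusted over the list alone), led by the sterol regulator INSIG1 (-0.58) and the squalene epoxidase SQLE (-0.56). In fatty acid synthesis 7 of 11 genes fell and 1 rose, as when adjusted over the list alone, led by the desaturase FADS2 (-0.96) and the acyl-CoA synthetase ACSL1 (-0.85), while ELOVL5 rose by 0.83. All 5 measured androgen-repressed genes fell, as when adjusted over the list alone, including the androgen-glucuronidating enzyme UGT2B17 (-1.05). Besides MET and DDC, the list held only UGT2B17 and its relatives UGT2B15 and UGT2B28, which are alike in sequence. Their probe sets were not checked for shared sequence, so these falls may not be independent. MET fell by 1.11 on its brighter probe set, but its other probe set differed by 0.26 and stood for the gene when any control array was left out.

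Camera gave adjusted p values of 5.2e-07 for the amino acid response, 8.1e-05 for androgen-repressed genes, 0.00147 for the unfolded protein response, 0.00147 for cholesterol synthesis and 0.00806 for fatty acid synthesis. None of these calls held with an estimated correlation: adjusted p = 0.193 with an estimated correlation for the first 4 and 0.375 for fatty acid synthesis, although 4 lists had an unadjusted p under 0.05, and fry called 15 lists. Without probe sets of the _x_at and _s_at kinds, which can match several transcripts, 1 list was called, the amino acid response.

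Genes tied to PSMA's enzymatic products did not move one way. Of 19 folate uptake and one-carbon genes, 8 rose and 4 fell (9 and 5 adjusted over the list alone). MTHFD2L was lower by a log2 fold change of -0.81 and GGH, which trims glutamate from folates, by -0.70. None of 9 glutamate receptor genes passed (0 adjusted over the list alone), with GRIN2B at 0.35 and GRM2 at 0.32. In glutamate transport and metabolism 2 of 17 rose and 6 fell, as when adjusted over the list alone, including the transporter SLC1A1 (-0.79) and the glutathione synthesis subunit GCLM (-0.61). Of 23 PI3K-AKT-mTOR components, 5 rose and 8 fell (5 and 10 adjusted over the list alone). GNAQ rose by 0.66, and PDPK1 fell by 0.54 on a probe set that its other probe sets, at -0.04 and 0.08, did not follow. FOXO targets had 3 rises and 3 falls in 14, as when adjusted over the list alone, such as SESN1 (0.53) and CITED2 (-0.60). Camera called none of these lists, with adjusted p values from 0.312 to 0.842, whereas fry called glutamate receptors higher (adjusted p = 0.0362) and glutamate transport and metabolism lower (adjusted p = 0.0102).

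Androgen-induced genes were split: 11 of 22 rose and 4 fell, as when adjusted over the list alone (camera adjusted p = 0.0657). Camera called this list under 4 alternatives, but not with an estimated correlation (adjusted p = 0.569), and fry called it higher (adjusted p = 0.00104). MAF, the stress-responsive NDRG1 (1.71), the lipid phosphatase PLPP1 (1.11) and the methyltransferase GNMT (1.02) rose at least 2-fold, while KLK3, which encodes prostate-specific antigen, fell by 0.71. Antigen presentation genes had 6 rises and 1 fall in 13, as when adjusted over the list alone (camera adjusted p = 0.0657), with HLA-E at 0.55 and PSMB9 at 0.63; camera called it under 4 alternatives, but not with an estimated correlation (adjusted p = 0.691), and fry called it higher (adjusted p = 0.011). The other HLA-E probe sets differed by 0.30 and 0.35, and its call was lost without _x_at and _s_at probe sets. The call of PSMB9, a dim gene, was lost under several alternatives. HLA genes lie on chromosome 6, whose measured genes had a median of 0.14, and the counts for this list were not corrected for that shift. In the TGF-beta and BMP list 7 of 12 rose and 2 fell, as when adjusted over the list alone, and BAMBI fell while ID3 rose by 0.86. KLK3, ID3, EDEM1 and ELOVL5 were chosen as examples after their values were seen. Of 15 p53 targets, 6 rose and 1 fell, as when adjusted over the list alone. The fall was in the cytokine GDF15 (-1.50, or -0.61 with the mean of all its probe sets, of which no other passed the filter). The ERK feedback inhibitors SPRY2 (1.19) and SPRY1 (1.02) rose within a list of immediate-early and feedback genes in which 5 of 19 rose and 3 fell (5 and 4 adjusted over the list alone). SPRY2 rose from a control level under log2 4, or by 0.79 with low values raised to 4. Camera adjusted p values for the last 3 lists ran from 0.298 to 0.842, and fry called the immediate-early and feedback genes higher (adjusted p = 0.011).

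Camera called none of the proliferation, housekeeping and signalling lists that follow, although fry called polyamine metabolism (adjusted p = 0.00881) and MYC and ribosome biogenesis (adjusted p = 0.0135). Of 23 G1/S genes 3 rose and 3 fell (2 and 3 adjusted over the list alone), and MCM3 rose by 0.54 and RRM2 by 0.38. Of 26 G2/M genes 5 rose and 6 fell, as when adjusted over the list alone, including CENPE (-0.81). Oxidative phosphorylation had 1 rise, in COX5B (0.56), and 4 falls in 24 (1 and 2 adjusted over the list alone). In hypoxia and glycolysis 4 of 24 rose and 1 fell (3 and 0 adjusted over the list alone), with KDM3A at 0.46. MYC and ribosome biogenesis had 5 rises in 18, including WDR43 (0.53), and polyamine metabolism 3 rises and 3 falls in 12, including SAT1 (0.65). In the microRNA machinery 3 of 8 rose and 3 fell, with TARBP2 at 0.43. These 3 counts did not differ when adjusted over the list alone. Type I interferon-stimulated genes had 3 rises and 3 falls in 18, also when adjusted over the list alone, with IFI44 at 0.70 and IFIH1 at -0.51. Of 9 NF-kB targets 2 rose (1 adjusted over the list alone), and of 11 cancer-testis antigens 3 rose and 3 fell (3 and 4 adjusted over the list alone), the largest fall being that of PAGE1. Both measured WNT targets, RNF43 (-0.18) and LEF1 (-0.09), failed the test, also when adjusted over the list alone. Camera adjusted p values for these lists ran from 0.464 to 0.942. Median and mean differed in sign for the FOXO, G1/S, G2/M and luminal lists, whose camera direction was lower.

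**Figure D4:**
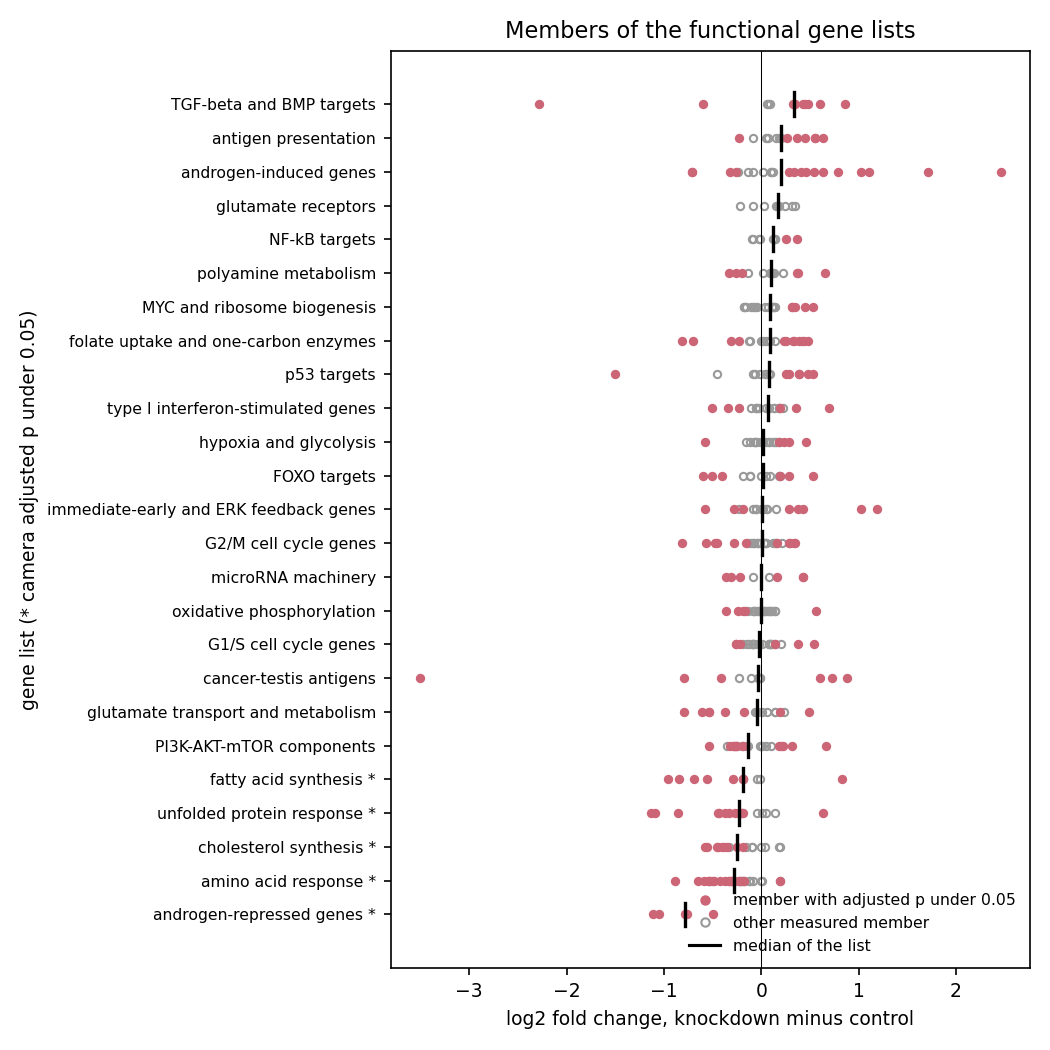
Log2 fold change of knockdown minus control (horizontal axis) for each measured member of 25 functional gene lists (vertical axis); filled points have an adjusted p under 0.05 and bars mark list medians. The 5 lists marked with an asterisk, all with medians under 0, passed camera at its preset correlation, and none of them with an estimated correlation (adjusted p = 0.193 to 0.375).

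Camera called none of the marker lists. Luminal prostate markers had 2 rises and 6 falls in 15, as when adjusted over the list alone, and the luminal keratin KRT19 rose 3.18-fold. Basal markers had 2 rises and 1 fall in 6, and the mesenchymal list 1 rise, in SNAI2 (1.49), and 1 fall in 7. Fibroblast and smooth muscle markers had 2 rises in 8, including COL3A1 (1.01, and 0.48 on its other probe set). These counts were the same when adjusted over the list alone. Of 6 neuroendocrine markers 1 fell, ENO2 at -0.58 (0 adjusted over the list alone). Camera adjusted p values for these lists ran from 0.154 to 0.917, whereas fry called luminal markers lower (adjusted p = 0.0447) and fibroblast and smooth muscle markers higher (adjusted p = 0.0144). The leukocyte genes CD3E (0.05) and ITGAM (0.02) and the endothelial genes PECAM1 (0.09) and VWF (0.01) lay near the filter level or did not differ beyond the spread of the arrays, also when adjusted over the list alone.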

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

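The tests in this part on signal toward the 5′ end were chosen after the result was seen.

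Among probe sets paired with several gene symbols or none, which the gene tests left out, 10 were at least 2-fold higher in knockdown than in control arrays and 22 were lower. A ribosomal RNA control probe set, also outside the gene tests, was 0.53 higher in knockdown arrays on the log2 scale, with every knockdown array above every control array, while 3 probe sets for another ribosomal RNA differed by -0.25, -0.16 and -0.15.

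The count of 173 genes changed at least 2-fold was larger than in any other grouping of the arrays. Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave as many, and the highest other split gave 0. For gene lists the real split called 5, again 1 of 10 splits, and the highest other split called 3. With 10 splits the share cannot fall under 0.1, so the splits are too few for a share under 0.05. Each other split also mixed arrays of both groups, so any difference between the groups widened its spread and made low counts likely.

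A candidate technical explanation for the differences is a loss of signal toward the 5′ end of transcripts in the knockdown arrays, since their control probe sets differed. Such a loss lowers signals, and genes could rise only if normalization lifted what it spares. The 3′ probe sets (10) of beta-actin, GAPDH and the poly-A controls, which such a loss would spare, differed between groups by log2 values of -0.27 to 0.06, and by at most 0.53 with 2 SE added, where a 2-fold rise needs 1. For the 23 rises at signal levels these probe sets cover, this test cannot decide. The level of the poly-A controls also depends on the amount added, which is not known for either group. The 3′ probe sets of beta-actin and GAPDH, whose RNA comes from the cells, differed by -0.18 and 0.06, but only at log2 12.85 or more. The other 57 rises lay below the dimmest of the 10 probe sets, at 7.96 on the log2 scale. For all rises such a loss therefore stays open, as do other differences in array processing. For the falls it stays open too: the poly-A control dap, which does not come from the cells, was lower by a log2 difference of -0.97 in its 5′ relative to its 3′ signal. Of 28 genes that fell at least 2-fold and had another probe set, the dimmest probe set fell by more in 28.6%, but positions along the transcripts were not used here. Only the brightest probe set had been selected for its fall, which lowers this share whatever the cause. Array processing and knockdown cannot be told apart for these falls, because the control probe sets separate the arrays exactly by group.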

How the results depend on the processing

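All alternatives were fixed before the data were examined except the subtraction of chromosome medians, which was chosen after seeing the data. The counts of 80 genes higher and 93 lower stayed within 1.5 times under every alternative except the size threshold and the unit tested. With no minimum fold they were 1793 and 1526, and at 1.5-fold 280 and 323, as looser thresholds must give more. At the level of probe sets 208 were lower, while the number higher stayed within 1.5 times; the cause was not tested. Leaving out 1 array gave 69 to 89 higher and 82 to 98 lower. Subtracting chromosome medians gave 72 and 97, of which 156 were among the 173. Rescaling moved the median of all genes to at most 0.061. The FOLH1 change kept its direction in all alternatives that measured it, and its call was lost with values raised to 4 (-0.79, adjusted p = 0.0771). No FOLH1 value lay under log2 4, the lowest being 5.341, so raising low values left FOLH1 itself unchanged. The loss came through the other genes that enter the variance model and the adjustment, with 11963 genes tested under that alternative against 9241. The 5 list calls became 1 without _x_at and _s_at probe sets, where the androgen-repressed list had too few members for a test (as with the filter at log2 6 and the mean of all probe sets), 0 with an estimated correlation and 15 with fry, which tests another question. The cause was not tested for the first 2. Camera also called androgen-induced genes under 4 alternatives (the filter at log2 6, the mean of all probe sets, trend and robust, and without knockdown replicate 2). It called antigen presentation under 4 (the mean of all probe sets, array weights, and without control replicate 3 or knockdown replicate 3).

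Whether the replicate numbers pair the arrays is unclear. Correlations of same-numbered deviations were 0.11, 0 and 0.18, against -0.15 to 0.05 for arrays with different numbers. In each group, 2 of 3 arrays correlated best with their own number. With the replicate number as a block, 80 genes were higher, 93 lower and 5 lists called, and the FOLH1 log2 fold change was -0.79.

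Among 81 other named genes, signs turned for CD3E (-0.08) and ITGAM (-0.02) with array weights and for DICER1 (-0.01) with the mean of all probe sets. Leaving out any control array turned MET, through the switch of probe set, for a range of -1.23 to 0.32 over the arrays left out. The ranges were -0.01 to 0.15 for CD3E, -0.02 to 0.08 for ITGAM and -0.08 to 0.09 for VWF, none of them past the test. Across the same genes, 17 calls were lost with the sign kept under other alternatives and 28 when 1 array was left out. A gene was counted once for each alternative that lost its call. Most of these losses were of genes with small changes, such as SFN and the dim LIF, PSMB9 and S100A2. The counts leave out calls lost with a turned sign, as for MET when a control array was left out (limma adjusted p = 0.0968, 0.0559 and 0.165). Genes near log2 4 lie close to background, and their folds depend on its correction.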

Other observations

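The genes and tests in this part were chosen after the values were seen. The interferon-induced membrane genes IFITM1, IFITM2 and IFITM3 rose 2.61-, 3.67- and 3.05-fold, while the type I interferon list had as many falls as rises. The reductases AKR1C1 and AKR1C2 rose 2.77- and 3.04-fold on their brightest probe sets, while the other AKR1C1 probe sets differed by 0.60 and 0.03. Their relative AKR1C3 rose by 0.94 on the log2 scale from a level under log2 4, or by 0.23 with low values raised to 4. The glucuronosyltransferases UGT2B15 and UGT2B28 fell, with log2 fold changes of -0.78 and -0.76. The receptor IGF1R rose 2.22-fold, the adaptor IRS1 2.26-fold and the signalling inhibitor SOCS2 2.01-fold, whereas IRS2 (0.00) and INSR (0.19) did not pass the test. The other probe sets of IGF1R and SOCS2 differed by 0.76 and 0.58. No enrichment was tested for these genes. The growth factor receptor FGFR3 rose 3.86-fold, and the relaxins RLN1 and RLN2 were 2.51- and 4.51-fold lower. Members of the IFITM, AKR1C, UGT2B and relaxin families are alike in sequence, and their probe sets were not checked for shared sequence.

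Most measured genes of the metallothionein cluster, whose products bind zinc and copper, fell, as did their neighbour NUP93, a nuclear pore gene, in RefSeq order on GRCh38.p14. MT2A, MT1F, MT1G, MT1H and MT1X were 2.80- to 3.20-fold lower and MT1E 1.88-fold lower (-0.91, and -0.26 on its other probe set), whereas the dim MT3 (-0.02) and MT4 (-0.27) did not pass the test. The related MT1HL1, not among the measured genes of this segment, was 2.67-fold lower. Its probe set is of the _x_at kind and may match other metallothioneins, so its fall cannot tell the explanations below apart. Probe sets that metallothioneins share could spread 1 fall over several members, but do not account for NUP93, at -1.96 on its single probe set. Lower copy number or silencing of the segment stays open, as the 10 nearest measured genes had a median of -0.12, as low as 10.8% of runs of 10 genes. The 4 brightest of these fell (ARL2BP -0.67, OGFOD1 -0.61, HERPUD1 -0.44 and NUDT21 -0.33), CES1 rose by 0.36 and the others did not pass the test. Chromosome 16, which carries the segment, was lower as a whole, with a median of -0.10 and 68.3% of its genes lower. Lower metal-responsive transcription also stays open, since SLC30A1, a metal-responsive zinc exporter elsewhere in the genome, was lower by a log2 fold change of only -0.16 (adjusted p = 0.0322). The importer SLC39A8, no part of this test, had log2 fold changes of -1.39, -1.67 and -0.33 on its probe sets.

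Genes of some chromosomes shifted as a whole. Of 151 measured genes on chromosome 13, 84.1% were lower in knockdown, with a median log2 fold change of -0.27, while the medians of chromosomes 21 and 6 were 0.18 and 0.14. Against signal level and gene length as the source, 0 of 10000 random gene sets matched on both had a median as low. The two-sided p of 2.0e-04, the smallest these draws can give, was 7.7e-04 after adjustment over 23 chromosomes, of which 8 passed, chromosomes 16, 7, 4, 22 and 2 (medians of -0.10, -0.09, -0.03, -0.02 and 0.06) besides the 3 above. The draws treat genes as independent units, so these p-values do not measure the spread between arrays or cultures. The medians of 3 consecutive parts of chromosome 13, with nearly equal numbers of genes, ran from -0.30 to -0.25, which is consistent with a copy number difference between the cell populations compared, a hypothesis found on the same data. Whether such a difference arose by chance in a subline or with the knockdown was not tested.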
